A study of Mus musculus with 2 samples.

How the data were processed

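H3K36me3 was measured by chromatin immunoprecipitation and sequencing in embryonic day 11.5 mouse midbrain, in 2 biological replicates of 1 group. Per the labels, each replicate is a pool of embryos of both sexes with 3 technical replicates combined, and fragments of 300 to 500 bp were used. The labels call the samples biological replicates, so the spread between them includes differences between pools as well as the assay. Variation between single embryos is averaged within each pool and is not measured. Replicate 2 covered 1.94 times the bases of replicate 1, and the SDs include this difference between the lists.

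The authors deposited 4 peak lists in narrowPeak layout on mm10. Per the description files deposited with the samples, each replicate list was called on the filtered alignments of that replicate with a control, the pooled list on the alignments of both replicates, and the replicated list was derived from the pooled list and both replicate lists. The peak caller, its version, its settings and the replication rule are not given in the sources used here. For each peak the deposited fold enrichment is a ratio over the control, and the deposited −log10 values are those of the caller's p-value and q-value. The lowest −log10 p was 2.00 in both replicate lists and 2.05 in the pooled and replicated lists. A q-value of at most 0.05 was held by 71.2% of the replicate 1 peaks and 93.8% of the replicate 2 peaks. Fold enrichments were used to describe, rank or filter peaks, and in the replicate correlation and the tests on the pooled list. A comparison of the X chromosome with autosomes used them too. Because no read counts are given, no interval for counting error could be computed, and precision rests on the spread between replicates, with n = 2.

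Gene models came from GENCODE mouse release 21 on GRCm38, the same build as mm10. Protein-coding genes on chromosomes 1 to 19 and X with a gene record of at least 1000 bp were tested. The covered share of a gene is the percent of its bases, from start to end of the gene record, under the peaks of a list. A gene is called marked at 10% or more in each replicate. Coordinates are 1-based. Shares are means of both replicates with their SD.

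Chance levels came from 100 circular shifts of all peaks along each chromosome past its first 3 Mb, with a one-sided p in the observed direction whose smallest value is 0.0099. Coverage along genes and of exons against introns was averaged per chromosome and tested by a two-sided sign-flip permutation test over 20 chromosomes (100000 resamples). Gene lists and the X chromosome were tested with two-sided Fisher's exact tests, adjusted by Benjamini-Hochberg over 25 lists and over 6 direct comparisons. In these tests genes are the units, so the p-values describe these peak lists, not the spread between embryos, and neighbouring or related genes are not independent. Overlap between lists required 50% of a peak's length. Comparisons of fold enrichment between lists instead took any overlap of 1 bp and the highest fold among the peaks touched. Domains joined peaks within 3 kb.

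The 25 gene lists, the tests, the rule for named genes and the alternatives below were fixed before the data were examined. The lists were midbrain patterning, forebrain patterning, hindbrain and trunk Hox, neural progenitor, neuronal differentiation, mature synapse, astrocyte and oligodendrocyte, dopaminergic neuron, cell cycle, ribosomal protein, proteasome, splicing factor, H3K36 methylation, imprinted, Zfp zinc finger, olfactory and vomeronasal receptor, replication-dependent histone, clustered protocadherin, erythroid, endothelial, macrophage and microglia, mesenchyme and neural crest, liver, heart and skeletal muscle, and germline and pluripotency genes. The rule took the 10 genes of at least 10 kb with the highest mean covered share, the 2 highest members and the lowest member of each list (ties to the longer gene), the 5 longest domains, and the 5 genes of at least 10 kb with the largest replicate difference in each direction. Genes named outside the rule are said to be. Alternatives were a stricter p (−log10 p of at least 5), other overlap minimums, equal numbers of peaks, the pooled or replicated list, either replicate alone, thresholds of 5% and 20%, genes without overlaps, gene bodies without the first 1 kb, other gene length minimums and promoter sizes, and 10000 length-matched random lists. Chosen after the data were seen were gene bodies without the last exon, autosomal genes matched to X genes on length and promoter CpG ratio, and the alternatives run on the length classes and on single named genes.

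The statistics were tested on simulated data, with 200 genes given peaks in 2 simulated replicates. Among the 21058 genes tested, 100% of these 200 were called marked. No other gene was, in a count that left out the 4629 genes that overlap another protein-coding gene. Background peaks were placed at random in the simulation, so this count does not measure false marks in the data. This recovery holds for the coverage planted and does not give the sensitivity for genes near the marking threshold. Of 24 random lists 0 passed. With only the planted genes marked, against 17.4% of genes in the data, random lists had little chance to pass. Their count therefore does not measure false positives in the data. With a 3′ and exon bias built in, both sign-flip tests gave a permutation p of 1e-05, and with none they gave 0.623 and 0.789. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and matplotlib 3.10.9. Peaks on the Y chromosome and on unplaced sequences were left out of the comparisons, 52 peaks of replicate 1 and 39 of replicate 2. Some members of the lists had no matching protein-coding gene of sufficient length, and the numbers tested are given with each list.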

Results

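Trimethylation of histone H3 at lysine 36 (H3K36me3), a modification laid down over the bodies of transcribed genes, was profiled by chromatin immunoprecipitation and sequencing in mouse midbrain at embryonic day 11.5. The midbrain at this age is a neuroepithelium in which dividing progenitors and the earliest neurons lie side by side. There was 1 group of 2 biological replicates of strain B6NCrl, each pooled from male and female embryos, 109 embryos in replicate 1 and 88 in replicate 2. The deposited values are peak lists on mm10, which hold positions, fold enrichments and p-values but no read counts, so the sequencing depth is unknown. Replicate 1 had 112237 peaks over 31.4 Mb and replicate 2 had 151189 peaks over 61.1 Mb. Median peak width was 226 bp in replicate 1 and 295 bp in replicate 2.

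To ask which genes carried the mark in this tissue, the share of each gene body under peaks was computed for 21058 protein-coding genes. Fasn, the fatty acid synthase gene, had the highest covered share among genes of at least 10 kb, 72.5% ± 14.2 (SD, n = 2), on chromosome 11 at 120805846 to 120824547. Next came Hjurp, the chaperone of the centromeric histone variant, at 72.5% ± 7.03 (chromosome 1, 88262471 to 88277633), and Prrc2a at 70.7% ± 9.44 (chromosome 17, 35149076 to 35164897). The rest of the 10 highest were Zfp110 at 69.5% ± 14.0, Zfp606 at 68.4% ± 18.5, the splicing factor gene Sf1 at 67.9% ± 16.8, the cell polarity gene Scrib at 66.7% ± 18.2, Thoc3 of the mRNA export complex THO at 66.0% ± 23.9, the fatty acid desaturase gene Scd2 at 65.6% ± 9.82 and Prr12 at 65.2% ± 19.3. None of these 10 overlapped another protein-coding gene, and all 10 had the larger share in replicate 2.

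Genes with at least 10% of the body under peaks in both replicates are called marked, and 3670 of the 21058 genes (17.4%) met this. With the peaks of both replicates shifted together around each chromosome, a mean of 742 genes met it (range 632 to 845 over 100 shifts, one-sided p = 0.0099 by permutation of positions, the smallest these shifts can give). No peak fell in either replicate on 8033 genes. The threshold was reached by 3755 genes in replicate 1 and by 6323 genes in replicate 2, so without replicate 1 the count would be 6323. Of the genes at the threshold in replicate 1, 97.7% were also there in replicate 2. Of those in replicate 2, 58.0% were also there in replicate 1. Covered shares correlated with a Spearman rho of 0.873 across all genes and 0.721 across marked genes (genes are not independent replicates). The assay has no strand, and 1126 of the marked genes overlap another protein-coding gene.

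**Figure D1:**
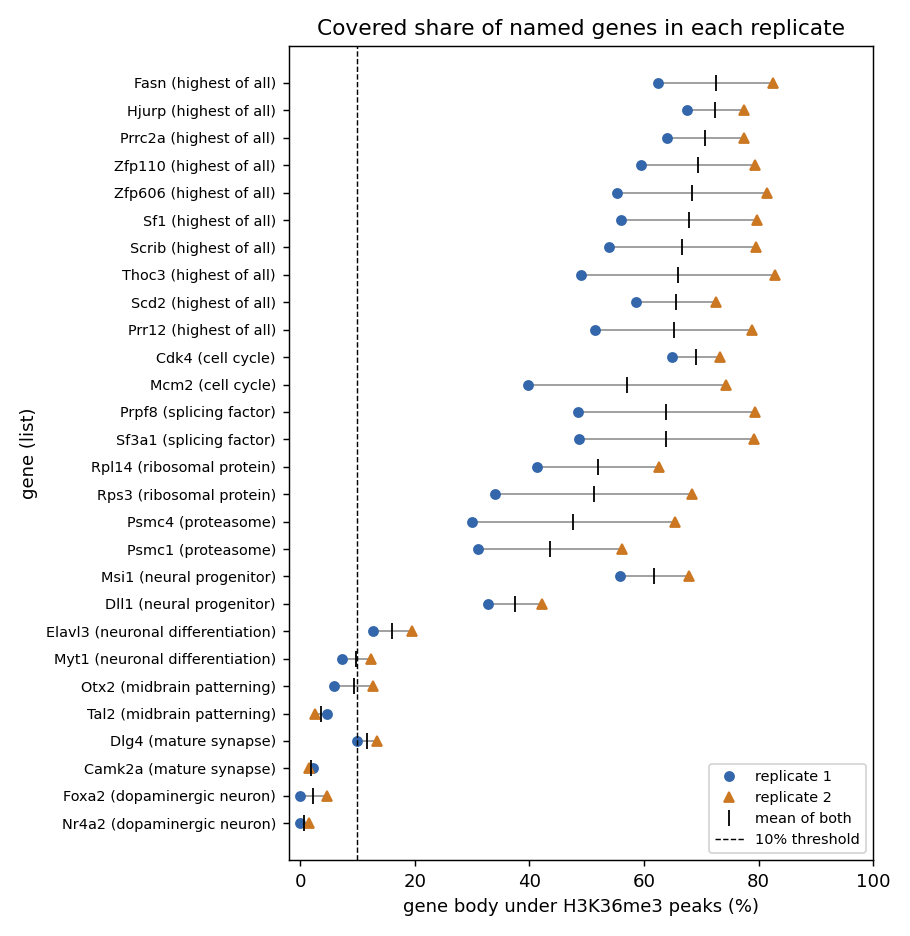
Share of the gene body under H3K36me3 peaks (x axis, %) for the 10 highest genes and for the highest members of 9 gene lists (y axis), with a circle for replicate 1, a triangle for replicate 2 and a tick for their mean. Fasn, Hjurp and Prrc2a exceed 60% in both replicates, whereas Otx2 lies at 5.98% and 12.8%, on either side of the dashed 10% threshold.

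Genes of proliferation were marked more often than other genes. In the cell cycle list, 26 of 29 genes (89.7%) were marked, against 17.3% of other genes (p = 3.68e-17, adjusted p = 3.07e-16, two-sided Fisher's exact test with Benjamini-Hochberg adjustment over 25 lists, of which 12 had an unadjusted p under 0.05). Cdk4, the cyclin D kinase, had 69.1% ± 5.98 (SD, n = 2) of its body covered and overlaps Tspan31. Mcm2, of the replicative helicase, had 57.1% ± 24.4, and the lowest member, Pcna, the sliding clamp of DNA polymerase, still had 12.3% ± 2.25. Genes of RNA and protein handling stood with them. Among splicing factors 22 of 24 genes (91.7%) were marked (p = 3.70e-15, adjusted p = 2.31e-14, Fisher's exact test), led by the spliceosome genes Prpf8 at 63.9% ± 21.9 and Sf3a1 at 63.9% ± 21.7. Hnrnpk, which overlaps another gene, was lowest there, at 7.60% in replicate 1 and 29.5% in replicate 2. Among ribosomal protein genes 20 of 27 (74.1%) were marked (p = 1.61e-10, adjusted p = 8.04e-10, Fisher's exact test), with Rpl14 at 52.0% ± 15.0, Rps3 at 51.2% ± 24.3 and Rpl15, which overlaps another gene, at 2.45% ± 3.47. Among proteasome genes 19 of 27 (70.4%) were marked (p = 1.94e-09, adjusted p = 8.10e-09, Fisher's exact test), with Psmc4 at 47.7% ± 25.02, Psmc1 at 43.6% ± 17.7 and Psmd14 at 1.43% ± 0.990.

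The enzymes and readers of the mark itself, and a family of DNA-binding proteins, also stood above other genes. Of the genes for H3K36 methyltransferases, demethylases and readers, 11 of 21 (52.4%) were marked (p = 0.00028, adjusted p = 0.001, Fisher's exact test). The demethylase gene Kdm4a had 58.3% ± 17.7 covered and Brpf1 had 49.7% ± 16.5, while Phf19 had 1.91% ± 1.48 (SD, n = 2). Setd2, the main H3K36 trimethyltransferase gene, had 20.1% ± 11.1 and was named after its value was seen. Of the genes named Zfp with a number, zinc finger proteins, 148 of 365 (40.5%) were marked (p = 1.08e-25, adjusted p = 1.35e-24, Fisher's exact test). Zfp110 at 69.5% ± 14.0 and Zfp869 at 68.9% ± 27.6 led them, and Zfp808 had no peak. With peaks at −log10 p of at least 5, the H3K36 list no longer passed (23.8%, adjusted p = 0.0627, Fisher's exact test).

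Part of the neural progenitor genes were marked. The threshold was met in both replicates by 8 of 26 (30.8%), which did not pass the test (p = 0.114, adjusted p = 0.142, Fisher's exact test). Msi1, an RNA-binding protein of neural stem cells, had 61.8% ± 8.50 of its body covered, and Dll1, a Notch ligand, 37.5% ± 6.74 (SD, n = 2), while Hes3 had no peak. The other marked progenitor genes, named after their values were seen, were Vim at 36.3% ± 22.7, Notch1 at 33.9% ± 9.30, Hes5 at 33.6% ± 27.2, Nes at 27.8% ± 8.15, Prom1 at 23.3% ± 12.6 and Rfx4 at 18.5% ± 9.55. Of 26 neuronal differentiation genes only Elavl3, an RNA-binding protein of young neurons, was marked, at 16.1% ± 4.85, and it overlaps another gene. Myt1 had 9.82% ± 3.57 and L1cam, which also overlaps another gene, had no peak (p = 0.0714, adjusted p = 0.122 for the list, Fisher's exact test). The median coverage of the progenitor list, 5.08% against 0.237% for 10000 random lists matched on length, passed at percentile 99.5. It also passed with peaks at −log10 p of at least 5 (23.1%, adjusted p = 0.0467), and with the pooled list the differentiation list passed at 0% (adjusted p = 0.0253, Fisher's exact test). Of the differentiation genes 15.4% reached the threshold in replicate 2 alone (adjusted p = 0.167, Fisher's exact test).

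None of the 22 midbrain patterning genes was marked (p = 0.0230, adjusted p = 0.0575, Fisher's exact test). Otx2, the homeobox gene of forebrain and midbrain, was highest, at 9.39% ± 4.82, then Tal2 at 3.61% ± 1.47, and Sim1 had no peak. The same held for the 20 forebrain patterning genes (p = 0.0363, adjusted p = 0.0756, exact test), with Lhx2 at 3.49% ± 2.22, Dlx5 at 2.70% ± 3.82 and Lhx8 without a peak. None of the 18 mature synapse genes was marked (adjusted p = 0.111, exact test). Dlg4, a scaffold of excitatory synapses, was highest at 11.7% ± 2.56 but had 9.86% in replicate 1, then came Camk2a at 1.95% ± 0.442, and Gria2 had none. No gene of the 10 in the dopaminergic neuron list was marked (adjusted p = 0.258, exact test), with Foxa2 at 2.32% ± 3.28, Nr4a2 at 0.754% ± 1.07 and Aldh1a1 without a peak. No lower count is possible for any of these lists without a marked gene, so their not passing does not show that they match other genes. The synapse list (unadjusted p = 0.0577) and the dopaminergic list (unadjusted p = 0.227, exact test) could not pass as lower here. In the astrocyte and oligodendrocyte list 1 of 16 genes was marked (adjusted p = 0.365, exact test). This was Cnp at 46.2% ± 11.96 (SD, n = 2), which overlaps the marked gene Dnajc7, whereas Aldoc had 8.22% ± 4.77 and Mobp no peak. In replicate 2 alone 3 of these lists passed as lower: midbrain patterning at 4.55% (adjusted p = 0.0131), forebrain patterning at 0% (adjusted p = 0.00263) and mature synapse at 5.56% (adjusted p = 0.0280, Fisher's exact test). The astrocyte and oligodendrocyte list stood at 12.5% there (adjusted p = 0.197, Fisher's exact test).

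No chemosensory receptor or Hox gene reached the threshold in both replicates. Of 1345 olfactory and vomeronasal receptor genes none was marked (p = 2.37e-116, adjusted p = 5.93e-115, Fisher's exact test), and the highest were Olfr530 at 4.09% ± 0.238 and Olfr1497 at 2.69% ± 3.81 (SD, n = 2), while Vmn2r7 had no peak. Of 39 Hox genes, which pattern hindbrain and trunk, none was marked (p = 0.00102, adjusted p = 0.00284, Fisher's exact test), with Hoxb9 at 2.05% ± 2.90, Hoxc6 at 0.642% ± 0.908 and Hoxa3 without a peak. Hoxc6 and Hoxa3 overlap other genes. Of 57 clustered protocadherin genes only Pcdhga4 was marked (p = 0.000357, adjusted p = 0.00112, Fisher's exact test), at 15.8% ± 8.11, named after its value was seen. Pcdhga7 at 16.1% ± 9.08 and Pcdhga3 at 15.8% ± 8.64 fell just short in replicate 1, Pcdhb14 had no peak, and all 57 overlap another gene. In replicate 2 alone 36.8% of the protocadherins reached the threshold (adjusted p = 0.323, exact test), and with the pooled list 17.5% did (adjusted p = 1, exact test). The Hox list did not pass with peaks at −log10 p of at least 5 (0%, adjusted p = 0.179, exact test), and at a threshold of 20% neither list passed. The shares were 0% in these cases, the lowest possible, so there the test could not have passed.

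Marker genes of other tissues were seldom marked at this threshold. In the erythroid (13 genes tested), endothelial (16), mesenchyme and neural crest (16), liver (16), heart and skeletal muscle (16), and germline and pluripotency (15) lists no gene was marked (adjusted p = 0.171 for erythroid and 0.122 for each of the others, Fisher's exact test). No lower count is possible, so lists of this size could not pass as lower in this test. Their highest members included the embryonic globin gene Hba-x at 5.10% ± 7.21 and Tal1 at 0.861% ± 1.22, the endothelial genes Kdr at 1.16% ± 0.702 and Tie1 at 1.01% ± 1.42, Foxc1 at 2.17% ± 3.06 and Alx4 at 0.488% ± 0.690. Of the liver genes, Apoa1 had 20.7% of its body covered in replicate 1 and 0% in replicate 2, and Apoa2 18.8% and 0%. Myog had 3.79% ± 5.36 and Tnni3 1.65% ± 2.34 among muscle genes, and Tex101 1.12% ± 1.59 and Piwil1 0.602% ± 0.345 among germline genes. Spta1, Emcn, Prrx1, Hnf4a, Myh6 and Dmrt1, the lowest members, had no peak. Alx4 and Tnni3 overlap other genes. In replicate 2 alone the same 6 lists passed as lower at 0% (adjusted p from 0.00869 to 0.0201, Fisher's exact test), while in replicate 1 alone 7.69% of the erythroid and 12.5% of the liver genes reached the threshold.

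In the macrophage and microglia list 2 of 16 genes were marked (adjusted p = 1, Fisher's exact test). Cd68, a lysosomal protein of macrophages, had 85.3% ± 4.52 of its 1.94 kb body covered (SD, n = 2) and lies 782 bp from the marked gene Eif4a1. Fcer1g had 13.5% ± 1.77 and lies 487 bp from the marked gene Ndufs2, and Adgre1 had no peak. Of 24 imprinted genes 2 were marked (adjusted p = 0.433, Fisher's exact test). These were Nnat, at 52.5% ± 31.03 and within the marked gene Blcap, and Zrsr1, at 19.9% ± 2.46 and within Commd1, while Ndn had no peak. In replicate 2 alone the imprinted list lay above other genes, at 37.5% (adjusted p = 0.504, exact test), and the histone list passed as lower at 0% (adjusted p = 0.00263, exact test). None of the 20 replication-dependent histone genes long enough to be tested was marked (adjusted p = 0.0756, Fisher's exact test). No lower count is possible there either. Hist1h2bc and Hist1h2be, which overlaps another gene, had no peak.

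**Figure D2:**
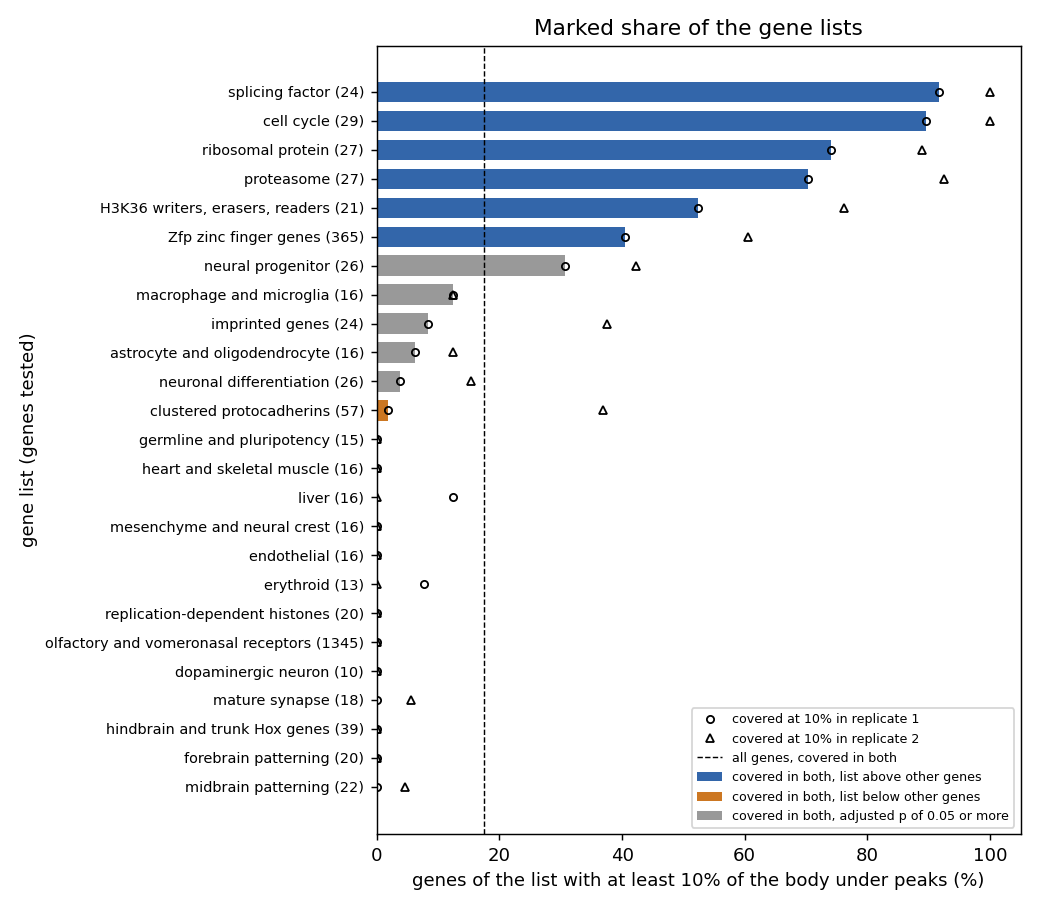
Share of each list's tested genes (y axis, number tested in parentheses) with at least 10% of the body under peaks (x axis, %). Bars give genes covered in both replicates, circles and triangles replicate 1 and replicate 2 alone, and the dashed line all genes (17.4%); splicing factor and cell cycle genes reach 91.7% and 89.7%, the Hox and olfactory lists 0%.

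Whether related groups differed from each other was tested directly in 6 comparisons. Neural progenitor genes (30.8%) were compared with neuronal differentiation genes (3.85%), a difference of 26.9 percentage points (p = 0.0238, adjusted p = 0.143, Fisher's exact test). Progenitor genes against astrocyte and oligodendrocyte genes (6.25%) differed by 24.5 points (adjusted p = 0.357, Fisher's exact test). Neuronal differentiation against mature synapse genes differed by 3.85 points (adjusted p = 1), and endothelial genes lay 12.5 points below macrophage and microglia genes, 0% against 12.5% (adjusted p = 0.968, Fisher's exact test). Midbrain against forebrain patterning genes, and midbrain patterning against Hox genes, were 0% against 0%, so nothing could differ. Both of these differences were 4.55 points in replicate 2 alone, and that of differentiation and synapse genes was 9.83 points (adjusted p from 0.721 to 1, Fisher's exact test). After correction 0 of 6 passed, and 1 of 6 had an unadjusted p under 0.05 (two-sided Fisher's exact test). The progenitor and differentiation lists did pass with the pooled list (30.8 points, adjusted p = 0.0249), without overlapping genes (32 points, adjusted p = 0.0392) and at a threshold of 5% (34.6 points, adjusted p = 0.0450, Fisher's exact test). At 5% the progenitor and the astrocyte and oligodendrocyte lists passed too (36.1 points, adjusted p = 0.0450, Fisher's exact test).

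Few genes on the X chromosome were marked. They were 16 of 877 (1.82%), against 3654 of 20181 autosomal genes (18.1%), a difference of -16.3 percentage points (p = 8.58e-52, two-sided Fisher's exact test). The X chromosome held 0.839% of the peaks of replicate 1 and 1.02% of those of replicate 2 but 6.53% of the genome. That last share also counts bases outside genes. On autosomes the marked share ran from 10.8% on chromosome 14 to 23.3% on chromosome 5. The 16 genes, listed after their values were seen, were led by Flna, which encodes the actin crosslinker filamin A, at 33.8% ± 10.6, the transcriptional regulator gene Hcfc1 at 32.1% ± 16.3, and Asmt, of the pseudoautosomal region that X shares with Y, at 28.8% ± 2.14 (SD, n = 2). They also included Kdm5c at 24.1% ± 11.5, Uba1 at 23.7% ± 14.9 and Ddx3x at 21.1% ± 14.6. In replicate 2 alone 7.30% of the X genes reached the threshold, and the difference was -23.7 points. The embryos were pooled from both sexes, so male and female chromosomes cannot be separated.

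**Figure D3:**
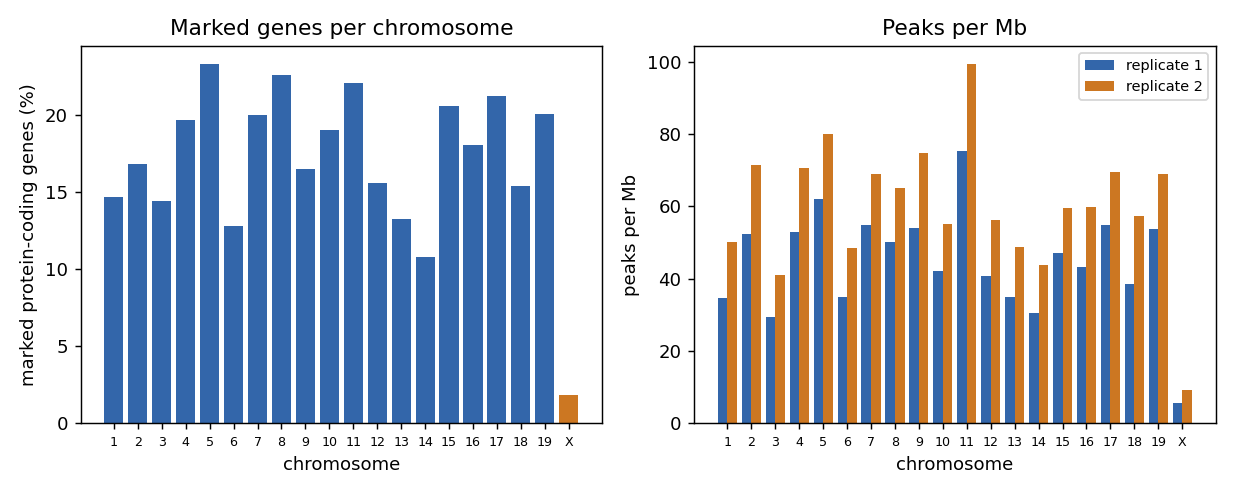
Share of protein-coding genes marked in both replicates (left y axis, %) and peaks per Mb in replicate 1 and replicate 2 (right y axis) for chromosomes 1 to 19 and X (x axes). Chromosome X has 5.61 and 9.21 peaks per Mb and 1.82% of its genes marked, the lowest values of the 20 chromosomes.

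The mark lay mainly over genes. Protein-coding gene bodies took 92.1% ± 2.81 of the peak bases (SD, n = 2), although they hold 40.3% of the genome, and 6.55% ± 2.43 lay outside all annotated genes. Exons took 25.6% ± 0.185, which was 6.54 times the mean of the shifted peaks (3.92%), and introns took 66.5% ± 2.62, against 37.6% for shifted peaks. Promoters, within 1 kb of a gene start, took 0.561% ± 0.204, below the 1.65% of shifted peaks. Each of these values lay outside the range of all 100 shifts (one-sided p = 0.0099 by permutation of positions, the smallest these shifts can give).

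Within marked genes coverage was higher toward the 3′ end. In 3318 marked genes of at least 5 kb, 38.1% of the bases from the gene midpoint to the gene end were covered, against 19.2% from the gene start to the midpoint. The difference was 18.8 percentage points (SD 1.96 over chromosomes), positive on 20 of 20 chromosomes, with a two-sided sign-flip permutation p of 2e-05. It was 13.8 points in replicate 1 and 23.9 in replicate 2. In the first of 20 bins along the gene 1.05% of bases were covered in replicate 1 and 1.64% in replicate 2. Coverage was highest in bin 17, at 30.6% and 54.2%, and in the first 500 bp past the gene end it was 18.2% and 36.6%.

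**Figure D4:**
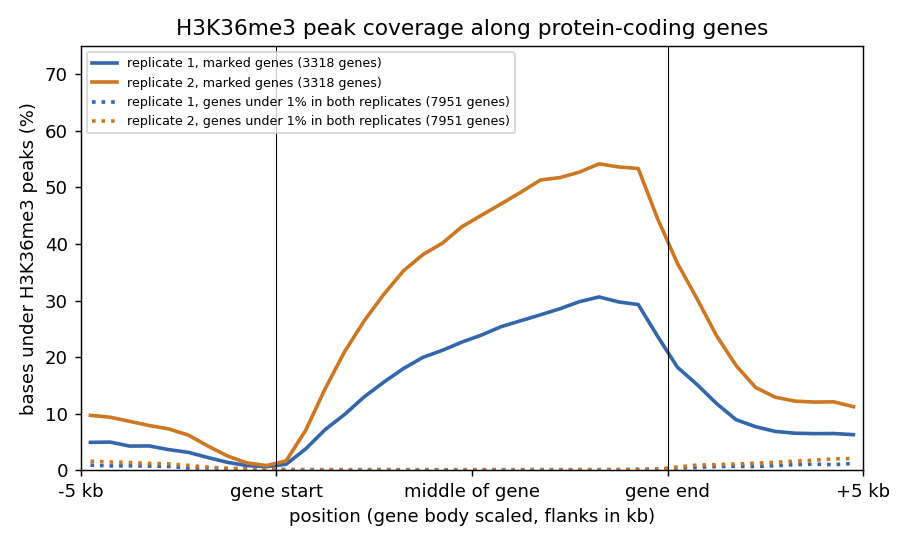
Mean share of bases under H3K36me3 peaks (y axis, %) along protein-coding genes of at least 5 kb (x axis: 5 kb upstream, the gene body scaled to 20 bins, 5 kb downstream). Solid lines are the 3318 marked genes and dotted lines the 7951 genes under 1% in both replicates; in marked genes the lines climb from 1.05% and 1.64% in the first bin to 30.6% and 54.2% in bin 17.

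Exons were covered more than introns. In 3603 marked genes with at least 2 exons, and without the first 1 kb, 40.9% of exon bases and 27.4% of intron bases were covered. The difference was 13.5 percentage points (SD 1.97 over chromosomes), positive on 20 of 20 chromosomes (two-sided sign-flip permutation p = 1e-05, the smallest these flips can give). Replicate 1 gave 10.8 points and replicate 2 16.1 points.

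The marked share varied with gene length. The marked share was 8.36% among the shortest genes (1000 to 3573 bp), 28.2% in length class 5 of 10 (12874 to 18469 bp) and 2.18% in the longest (113188 bp and above). Among those longest genes, 70.8% had at least 1 peak in each replicate, against 11.8% of the shortest.

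After joining peaks of the replicated list within 3 kb, the longest covered Ubr4, a ubiquitin ligase gene, for 101.2 kb on chromosome 4 (139389944 to 139491138), with 104 peaks over 50.3% of its bases and a highest fold enrichment of 5.54. Ubr4 overlaps another gene, Emc1. The next covered Trrap, a scaffold of histone acetyltransferase complexes, for 83.9 kb on chromosome 5 (144777643 to 144861561), and the transcription factor gene Gtf2i for 59.6 kb (chromosome 5, 134235920 to 134295532). Dync1h1, the dynein heavy chain gene, with the overlapping 1700001K19Rik, had a domain of 56.0 kb on chromosome 12 (110613276 to 110669300). Sptan1, the spectrin gene, with Wdr34, had a domain of 54.0 kb on chromosome 2 (29978462 to 30032416). There were 17661 joined domains with a median length of 1282 bp, of which 1711 reached 10 kb.

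**Figure D5:**
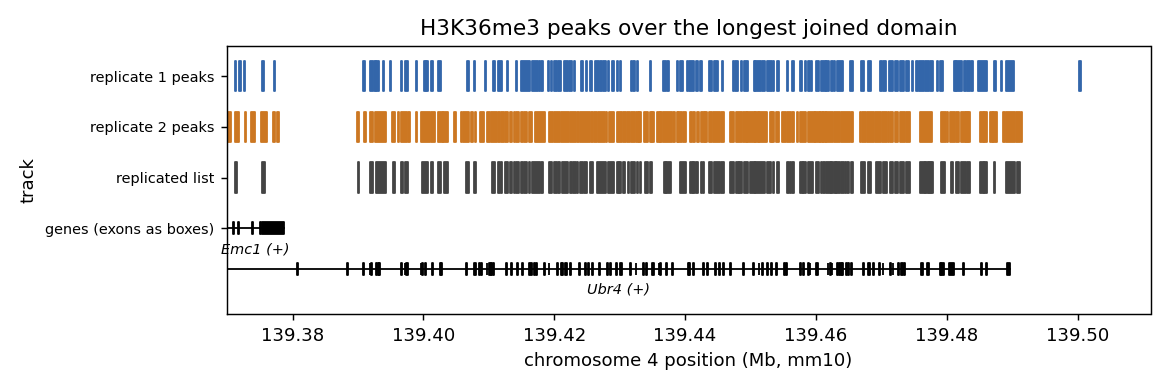
Map of chromosome 4 (x axis, Mb on mm10) around the longest joined domain, with boxes for the peaks of replicate 1, replicate 2 and the replicated list and, below, gene models with exons as boxes (y axis: tracks). The replicated list has 104 peaks inside the domain, which covers most of Ubr4, and replicate 1 and replicate 2 have 103 and 111.

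The share under peaks at some genes was far larger in 1 replicate. Among genes of at least 10 kb the largest excess in replicate 2 was at Tsr1 (25.6% and 71.9% in replicates 1 and 2), Hsp90b1, the endoplasmic reticulum chaperone gene (21.9% and 67.3%), Slc20a1 (20.97% and 66.0%), Ddx47 (28.7% and 71.5%) and Fus (25.5% and 67.4%). Tsr1 overlaps another gene, Srr. The largest excess in replicate 1 was smaller, at Chadl (17.6% and 6.73%), Dusp8 (21.6% and 10.7%), Ramp2 (8.16% and 0%), Gli1, a Hedgehog effector (7.19% and 0%), and Agap2 (6.83% and 0%). Chadl, Ramp2 and Gli1 overlap other genes. With 1 list per replicate these differences have no test.

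The replicates placed peaks at the same regions far more often than shifted peaks did. The widest peak of the replicated list lay over Hjurp (chromosome 1, 88262253 to 88270255), and its highest fold enrichment was 4.62 in replicate 1 and 8.01 in replicate 2. Of the replicate 1 peaks 50.5% had at least 50% of their length under replicate 2 peaks, against a mean of 2.64% for shifted peaks. Of the replicate 2 peaks it was 21.6%, against 1.18%. The Jaccard index of covered bases was 23.0%, against 0.904% (one-sided p = 0.0099 for all 3 by permutation of positions, the smallest 100 shifts can give). Replicate 2 covered 1.94 times the bases of replicate 1, which bounds the overlap. For the replicate 2 peaks the share was 39.0% with any overlap of 1 bp and 7.50% with 80% of the length.

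Heights of shared peaks were compared through the fold enrichments, which are the authors' own values per peak and were called separately in each replicate. Across 66650 replicate 1 peaks that touched a replicate 2 peak, log2 fold enrichment gave a Pearson r of 0.230 and a Spearman rho of 0.203 (SD over chromosomes 0.0253). Peaks are not independent replicates, and no p is given.

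The list of replicated peaks was a part of the pooled list. All 64382 of its peaks equalled a pooled peak in position and value, and 11944 of the 76326 pooled peaks were not in it. Of the pooled peaks 63.0% had at least 50% of their length under replicate 1 and 95.4% under replicate 2, and 58.5% under both, against 30.9% with 80% of the length. For the replicated list these were 71.8%, 97.5% and 69.3%. Of the 11944 left out, 43 lay under both replicates.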

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

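The results here were looked at only after the data were seen, and no explanation of them was tested. Peaks outside chromosomes 1 to 19 and X entered no comparison, so any signal there lies in data on which the results above are silent. On 1 unplaced sequence of the assembly replicate 1 had 15 peaks and replicate 2 had 10, with median fold enrichments of 1.82 and 1.52. The Y chromosome had 5 peaks in replicate 1, between 90737877 and 90742295. In replicate 2 it had 9 peaks, the first at 927515 and the last ending at 90745595. The replicated list held 9 peaks on the unplaced sequence and 3 on the Y chromosome.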

How the results depend on the processing

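Settings without the last exon, sets matched to the X chromosome on length and promoter CpG ratio, and the settings run on length classes and single named genes were chosen after the data were seen. Of the comparison values recomputed under the alternatives, 384 kept their direction and their side of the threshold, or stayed within the spread, 31 passed only under the alternative, 9 no longer passed (3 of them in the random list test described at its values), 20 moved and 11 took the other direction. Under every change of peaks, threshold or gene body, 6 lists were marked more often than other genes, but with peaks at −log10 p of at least 5 these included the neural progenitor list and not the H3K36 list. The X chromosome, the 3′ excess, the exon excess, the overlap between replicates and the 5 placement values passed in every setting run on them. Of the values for single named genes 348 kept their side of the 10% threshold, 12 fell below it and 12 reached it. The read depth is unknown, so a gene without peaks may carry the mark below what these lists could detect, and replicate 1 alone had 3755 genes at the threshold against 6323 in replicate 2. No paired analysis was possible because there is 1 group. The cause was not tested for any change listed here.

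Without replicate 1 or without replicate 2, the lowest and highest values were 3755 and 6323 for marked genes, 3 and 12 for lists marked less often, 1.75% and 36.8% for protocadherins, 8.33% and 37.5% for imprinted genes, 0% and 4.55% for midbrain patterning, 0% and 5.56% for mature synapse, 0% and 7.69% for erythroid, 0% and 12.5% for liver, 3.85% and 15.4% for neuronal differentiation and 6.25% and 12.5% for astrocyte and oligodendrocyte genes. Differences ran from 3.85 to 9.83 points for differentiation minus synapse genes, and from 0 to 4.55 points for midbrain patterning minus forebrain patterning or Hox genes. Shares were 0% and 0% for the forebrain patterning, histone, endothelial, mesenchyme, muscle and germline lists. With peaks at −log10 p of at least 5 there were 1687 marked genes, and the shares were 0% for Hox and 23.8% for H3K36 genes, which no longer passed, 23.1% for neural progenitor genes, which passed, and 8.33% for imprinted genes. With the replicated list neuronal differentiation genes stood at 0%. With the pooled list they also stood at 0%, protocadherins at 17.5%, which did not pass, the difference of progenitor and differentiation genes at 30.8 points, which passed, and that of differentiation and synapse genes at -5.56 points.

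At a threshold of 5% there were 5773 marked genes and 13 lists marked less often. The shares were then 4.55% for midbrain patterning, 7.69% for neuronal differentiation, 5.56% for mature synapse, 33.3% for imprinted genes and 29.8% for protocadherins, and 0% for the forebrain patterning, histone, erythroid, endothelial, mesenchyme, liver, muscle and germline lists. Progenitor genes exceeded differentiation genes by 34.6 points and astrocyte and oligodendrocyte genes by 36.1 points, and both passed. At 20% there were 1478 marked genes and 1 list marked less often, with 0% for Hox genes and protocadherins, which no longer passed. Without overlapping genes 16.7% of macrophage and microglia genes were marked, and progenitor genes exceeded differentiation genes by 32 points, which passed. Without the first 1 kb 5 lists were marked less often, midbrain and forebrain patterning stood at 0%, and differentiation minus synapse genes was -1.56 points. Without the last exon that difference was -1.21 points and 2.86% of protocadherins were marked, which did not pass. Among random lists matched on length, the median coverage lay at percentile 10.4 for protocadherins, 48.5 for Hox, 8.11 for olfactory and vomeronasal receptor, 89.4 for imprinted, 74.5 for neuronal differentiation and 99.5 for neural progenitor genes. The neural progenitor list passed, with an adjusted p of 0.0371. For the Hox and receptor lists this test decides nothing, because their median was 0% and left no room below it. It does not count against the lower marked shares of these lists. The protocadherin median was 0.117%, against a random median of 0.264% and a lowest random median of 0%. There was room below the protocadherin median, and that list did not pass. Lower coverage of protocadherins than of genes of like length was therefore not shown.

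With any overlap of 1 bp, 71.7% of the pooled peaks lay under replicate 1, 96.8% under replicate 2 and 68.5% under both, and for the replicated list 80.9%, 98.5% and 79.4%. With 80% of the length these were 38.9%, 89.3% and 30.9% for the pooled list and 43.4%, 90.5% and 36.7% for the replicated list.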

Other observations

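The gene family, long non-coding RNA and flank tests, the test of a stricter p in the pooled list, and the removal of the last exon for Zfp genes were chosen only after the results were seen. Families of general gene expression were marked more often than other genes. Of the DEAD and DEAH box RNA helicases 36 of 52 were marked (adjusted p = 4.13e-15, two-sided Fisher's exact test over 18 families), with Ddx39b at 63.3% ± 13.7 and Ddx56 at 63.2% ± 12.3 (SD, n = 2). Of the translation initiation factors 33 of 54 were marked (adjusted p = 8.06e-12, Fisher's exact test), with Eif4g2 at 63.9% ± 16.4 and Eif3l at 59.9% ± 20.1. Aminoacyl-tRNA synthetases (22 of 38), nucleoporins (14 of 21), mitochondrial ribosomal proteins (31 of 75), RNA polymerase II (9 of 13), Mediator (13 of 30) and Integrator subunits (8 of 14), kinesins (16 of 38) and chromodomain helicases (6 of 9) also passed, with adjusted p from 1.13e-07 to 0.002 (Fisher's exact test). The mitotic kinesin gene Kif20a had 52.3% ± 20.1 of its body covered and the chromatin remodeller gene Chd4 59.3% ± 12.7. Potassium channels (0 of 94), keratins (0 of 53), collagens (1 of 45), Wnt and Fgf ligands (1 of 41), Gpr receptors (4 of 73) and solute carriers (38 of 343) were marked less often (adjusted p from 1.13e-07 to 0.00721, Fisher's exact test). The marked collagen gene was Col2a1, at 49.3% ± 6.83, and the marked ligand gene Fgf22, at 39.3% ± 9.88. Ubiquitin-specific proteases (14 of 55, adjusted p = 0.16) and Fanconi anaemia genes (1 of 10, Fancm, adjusted p = 1, Fisher's exact test) did not pass.

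Of 4818 long non-coding RNA genes that overlap a protein-coding gene or lie within 5 kb of it, 319 (6.62%) were marked, against 10 of 4075 (0.245%) that lie apart (p = 2.20e-72, two-sided Fisher's exact test). The assay has no strand, so peaks of a protein-coding gene also count for a long non-coding gene on the same bases. This difference therefore does not show that the nearby long non-coding genes are themselves marked. The marked genes with the highest coverage among those apart were Gm26917 at 71.4% ± 7.56 (SD, n = 2), Snhg17 at 54.9% ± 18.1, Mir17hg, the host of a microRNA cluster, at 45.6% ± 19.3, Malat1 at 33.2% ± 10.6, Gm42418 at 32.1% ± 5.14 and Miat at 27.3% ± 7.88. Gm26917 and Gm42418 lie next to each other on chromosome 17 (39843013 to 39846341 and 39846958 to 39848788). Whether repeated sequence gave the peaks there was not tested. Xist, which is transcribed from the inactive X chromosome, had 0.457% ± 0.646. Around 210 marked protein-coding genes with no other gene within 10 kb, 8.87% of the bases of the 5 kb downstream were covered, against 0.132% of the 5 kb upstream. The difference was 8.74 points (SD 3.71 over chromosomes), positive on 20 of 20 chromosomes (two-sided sign-flip permutation p = 1e-05, the smallest these flips can give). The lowest p of the replicated list belonged to a peak over Mid1 on the X chromosome (169988466 to 169989579), with a fold enrichment of 7.83.

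Few genes on the X chromosome were marked, 1.82% against 18.1% on autosomes. The tables argue against gene length, promoter CpG ratio and soft-masked repeats in gene bodies as the whole cause: 10000 autosomal sets matched on length and promoter CpG ratio had a mean of 13.1% marked genes (lowest 9.12%), and sets matched on the share of soft-masked bases 17.3% (lowest 11.9%). The median soft-masked share was 23.15% for X genes and 22.57% for autosomal genes. Over whole chromosomes it was 45.5% for X, against 30.5% to 35.6% for the autosomes. Mapping itself was not measured, so poor mapping on X stays open. Lower enrichment per DNA copy on the X chromosome, as with 1 active X per cell, stays open without a test that decides it. Among genes with a promoter CpG ratio of at least 0.6, the 95th percentile of the strongest fold enrichment on X was 0.737 times that on autosomes in replicate 1 and 0.731 times in replicate 2, but any cause of fewer peaks on X lowers this value, as 3.16% of those genes on X and 30.6% on autosomes were marked. That male embryos have fewer X copies and so fewer reads there was not tested and stays open, since depth is unknown and the sexes were pooled.

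The pooled list held 76326 peaks, fewer than either replicate. A stricter p is argued against, since its lowest −log10 p exceeded that of the replicates by 0.0497. Fewer or rescaled reads behind the pooled calls are a candidate explanation, as at 91.9% of 14509 peaks with a fold within 10% of replicate 2 the pooled −log10 p was the lower. Dilution of replicate 2 by replicate 1 stays open. The pooled fold was below that of replicate 2 at 84.8% of 52279 pooled peaks that touched peaks of both replicates. Pooling with the lower replicate gives this in any case (medians 3.56 pooled, 3.39 in replicate 1 and 4.35 in replicate 2). Taking the highest fold among the replicate 2 peaks touched also raises the replicate 2 value. The caller's settings are not given in the sources used here, and no biological explanation was tested.

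Zfp zinc finger genes were marked in 40.5% of cases. The tables argue against gene length as the whole cause, since 10000 length-matched lists of other genes had a mean of 21.7% (highest 29.6%). Peaks did gather over the last exon, which holds the zinc fingers in this family: last exon minus the rest of the body was larger by 15.8 points in marked Zfp genes than in other marked genes (SD 15.7, higher on 16 of 19 chromosomes, two-sided sign-flip permutation p = 0.00047), as its prediction required, so this may be part of the cause. Without the last exon 28.4% of Zfp genes against 16.0% of others were still marked (adjusted p = 2.36e-08, exact test). The last exon alone therefore did not account for the difference. Those other genes were not matched on length, so whether length and the last exon together account for it was not tested. Reads shared between paralogs stay open, because Zfp genes with and without another Zfp gene within 100 kb differed by 0.738 points (40.9% and 40.1%, p = 0.915, exact test), and no biological explanation was tested.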
